A study of Melita plumulosa with 25 samples.

How the data were processed

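The 25 samples are 2-colour hybridisations to a custom Agilent array. Channel 1 held RNA of exposed animals and channel 2 reference RNA of unexposed animals of the same sediment, per the labels, each from 10 pooled animals. Groups and replicate numbers were taken from the sample titles, and the dye of each channel from the labels; each treatment has 3 arrays of one dye orientation and 2 of the other. The labels do not state separate cultures or tanks beyond the pools of 10 animals, nor whether 1 or several unexposed pools served a sediment, so p-values measure only the spread between these samples.

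Spot intensity in both channels, as the median over pixels with the median of the local background, was deposited by the authors as scanner output of Agilent Feature Extraction 10.7.3.1, per the file headers. The processed intensity values were background-subtracted and dye-normalized by that software, per the file headers. The log10 ratios in the same files are Cy5 over Cy3 of the processed signals, per the file headers. The log2 values in the authors' deposited value table matched the log10 ratios multiplied to base 2 and turned to exposed over unexposed, with r of at least 0.997 and slopes from 0.994 to 1.00 on every array, which settles scale and direction. Medians of its columns lay within 0.049 of 0, so any centring beyond that of the scanner software is unknown, and between 4438 and 6533 probes had a value per array.

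Median signals were corrected with normexp (offset 50) and normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3 with the data.table package (version 1.17.8). Mean signals had been planned; the files used here give median signals. Spots marked as outliers (330 over all arrays) were left out, and spots of 1 probe were averaged: 6696 probes had 2 spots and 1816 had 1. Ratios were turned to exposed over unexposed. Probes were kept where, in at least 1 treatment, at least 3 of the 5 arrays were well above background in at least 1 channel, which left 6636 of 8512. No spot was saturated. The number of arrays limits the precision; the median SE of a treatment's log2 change was 0.079.

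lmFit and eBayes were run on all 25 arrays with 1 coefficient per treatment and 1 for dye orientation, with two-sided tests and Benjamini-Hochberg adjustment at 0.05 over the tested probes. Treatments were tested against 0, and the doses within silt and within sand, silt against sand, and mixed against each were tested as contrasts. The dye coefficient passed for 1601 probes. Levels per channel were computed after loess and Aquantile, with no correction for dye. If the unexposed RNA of a sediment was 1 common reference, the test against 0 leaves out the control's own spread; an added fit counts the reference of each sediment as 1 control sample with the spread of the exposed arrays. Unchanged groups were simulated in 50 draws with 1 unexposed pool per sediment and in 50 with separate pools. In both, each array took a residual ratio profile drawn from the measured arrays. The 1 pool also took such a profile, so it varied as much as the ratio of 1 array, exposed channel included. The size of the counts simulated with 1 pool depends on this choice.

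The same fit was tested on simulated data with 200 changed probes of 6636. A log2 change of 0.5 was recovered for 77.6% of probes in the mixed sediment, 85.1% in silt at 200 mg/kg, 83.6% in silt at 500 mg/kg, 74.6% in sand at 10 mg/kg and 83.6% in sand at 60 mg/kg. The share of false calls was 2.73%, 4.64%, 4.15%, 7.18% and 6.09% in the same order. These simulations gave each array its own reference and each contig independent noise, whereas measured contigs moved together. The shares of false calls therefore need not hold for the measured arrays.

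By the rule set before the data were examined, named contigs are, per comparison, at most the 2 with the largest rise and the 2 with the largest fall among those past the threshold, with the same sign on every array of the treatment; contrasts had no such condition. No probe had a gene name, so 31 gene lists written beforehand were not used here, and the tests of list shifts were not run.

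Alternatives set beforehand were no dye coefficient, the processed signals, median centring in place of loess, no background correction, no filter and a strict filter (4933 probes) on dim probes, slide as a random or fixed block, the replicate number as a block, only the groups compared in the fit, the authors' value table, and leaving out each array. Alternatives chosen after seeing the data were the reference as 1 control sample, scan day as a block, the spike-in shift of an array as a covariate in 2 forms (tested at a shift of 0, and centred on its mean), and fits without 2 mixed or 2 silt arrays that stood apart. The arrays lay on 8 slides scanned on 2 days. The spike-in shift is the log2 ratio of exposed over unexposed for 10 spike-in RNAs relative to the animal RNA of the array. The amounts added are not given in the sources used here. The shift is taken from the ratios after loess. The mean Cy5 over Cy3 ratio of each spike-in over both dye orientations is taken off first, which removes a dye bias common to all arrays. The spike-in level of a single channel is taken before loess, over the animal probes well above background on all arrays. It is given as the departure from the mean of all arrays in the same dye. Its differences between channels need not equal the shift. Tables were prepared and plots drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.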

Results

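Gene expression was measured in Melita plumulosa, a small crustacean that feeds on sediment, after exposure to sediments carrying copper. Each of 25 arrays compared RNA of 10 pooled exposed animals with RNA of unexposed animals of the same sediment. There were 5 treatments with 5 arrays each: a 50:50 mixture of sand and silt with copper at 250 mg/kg, silt at 200 and 500 mg/kg, and sand at 10 and 60 mg/kg. The array held 8512 probes, each for 1 assembled contig, and 6636 were bright enough to test. On single arrays, between 52.2% and 82.1% of probes were well above background in the exposed channel and between 59.1% and 78.3% in the unexposed channel. The files do not pair contigs with gene names, so contigs are given by ID, and counts are counts of contigs. Several pairs of named contigs moved together across the arrays (mira_rep_c13549 and mira_rep_c17339, mira_rep_c7213 and mira_rep_c15791, mira_rep_c24438 and mira_rep_c9887); whether such contigs are parts or copies of 1 transcript is not known, so counts and overlaps do not stand for independent transcripts. Changes are log2 ratios of exposed over unexposed animals with their SE, and p-values are adjusted values from limma. If 1 pool of unexposed RNA served a sediment, the test of a ratio against 0 leaves out the spread between unexposed pools, so each count against unexposed animals is followed by the count obtained when the unexposed RNA of a sediment is treated as 1 control sample. Shares of called contigs with the sign of the call on a slide come from the arrays that made the calls, so they show where slides depart from a call and are no separate evidence for it.

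In the mixed sediment at 250 mg/kg, mira_rep_c15603 fell by 5.12 ± 1.00 (SE, n = 5; 34.8-fold; adjusted p = 0.000495). Contig mira_c1897 fell by 4.71 ± 1.00 (26.1-fold; adjusted p = 0.000963) and was well above background in all 5 unexposed samples but in 3 of the 5 exposed ones. Rises were smaller: the contig with the largest rose by 1.55 ± 0.52 (2.92-fold; adjusted p = 0.0288), and mira_rep_c16585, the next, rose 2.82-fold (adjusted p = 0.0360). Both rises rest on replicate 5, where the log2 ratios were 4.66 and 4.61; without it they were 0.81 (adjusted p = 0.244) and 0.75 (adjusted p = 0.292). Neither rise passed without replicate 1 (adjusted p = 0.0720 and 0.0866), with median centring (0.0554 and 0.0667), in a fit of the mixed arrays alone (0.187 and 0.205), or with the spike-in shift as a covariate tested at 0 (0.148 and 0.168) or centred on its mean (0.189 and 0.211). In these fits the log2 changes lay between 1.24 and 1.53.

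Across the array, 1969 contigs changed in the mixed sediment, 868 higher and 1101 lower, with a median fold of 1.37 among them; 253 changed more than 2-fold, 240 of them lower. With median centring in place of loess, 55.2% of calls were higher, against 44.1%. Within each of 5 slides, 93.2% to 99.3% of the 1969 contigs had the sign of the call, and with slide as a block 1693 passed. Without replicates 1 and 5, 1273 passed. On the main axis of the residual ratios of the silt and mixed arrays, after treatment and dye were fitted out, these replicates stood apart (-19.95 and -33.57). They did not stand apart in their correlation with the group (0.579 and 0.621, the others 0.600 to 0.634). With all arrays and the centred spike-in covariate 1217 passed. With the unexposed RNA counted as 1 control sample, 5 contigs passed, all lower. None of the contigs named above was among them (adjusted p = 0.525 for mira_rep_c15603 and 0.568 for mira_c1897). Simulated unchanged animals gave a median of 1922 calls (95% of draws from 378 to 3302) against 1 unexposed pool but of 0 against separate pools, where 0 of 50 draws reached the real count. Spike-in RNA was brighter in the exposed channel by 0.66 ± 0.35 (SD, n = 5) on the log2 scale relative to the animal RNA.

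In silt at 200 mg/kg, the falls in mira_rep_c13549 and mira_rep_c17339 were close in size. mira_rep_c13549 fell by 3.69 ± 0.51 (SE, n = 5; 12.9-fold; adjusted p = 4.96e-05) and mira_rep_c17339 fell by 3.67 ± 0.49 (12.7-fold; adjusted p = 3.37e-05). mira_c1844 rose by 3.06 ± 0.65 (8.31-fold; adjusted p = 0.00767) and mira_c23879 by 1.85 ± 0.46 (3.61-fold; adjusted p = 0.0223). None of the 4 passed in a fit of these 5 arrays alone (adjusted p between 0.0550 and 0.0947), though the log2 changes were close to those above: -3.68, -3.66, 2.96 and 1.86 in the same order. mira_c1844 also lost its call without replicate 2 (adjusted p = 0.0608) or replicate 3 (0.0563). mira_c23879 lost its call without replicate 1 (0.0774), 2 (0.0757), 3 (0.165) or 4 (0.0631), with median centring (0.0516) and with slide as a block (0.403). Its log2 change shrank to 1.16 with slide as a block and lay between 1.57 and 1.87 in the other fits listed.

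In total 273 contigs changed in silt at 200 mg/kg, 69 higher and 204 lower, of which 61 changed more than 2-fold. The share of higher calls was 25.3%, but 5.43% with median centring (92 calls), 40.4% with the scanner software's processed signals, 36.6% without background correction and 47.9% with the authors' own value table. The count was 152 without replicate 1, 130 without replicate 2 and 110 without replicate 3. On each of 4 slides all 273 contigs had the sign of the call, and 152 passed with slide as a block. limma called 0 contigs with the unexposed RNA counted as 1 control sample (89 at an unadjusted p under 0.05), and 0 in a fit of these 5 arrays alone (1230 unadjusted). Simulated unchanged animals gave a median of 1927 calls (95% of draws from 0 to 3696) against 1 unexposed silt pool but of 0 against separate pools, where 0 of 50 draws reached the real count. The spike-in shift was 0.27 ± 0.30 (SD, n = 5).

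In silt at 500 mg/kg, mira_rep_c8732 fell by 3.44 ± 0.39 (SE, n = 5; 10.8-fold; adjusted p = 1.53e-05) and mira_rep_c11266 fell by 3.27 ± 0.37 (9.62-fold; adjusted p = 1.53e-05). mira_rep_c11565 rose by 1.73 ± 0.40 (3.32-fold; adjusted p = 0.00872) and mira_rep_c15486 by 1.58 ± 0.39 (3.00-fold; adjusted p = 0.0144). These rises did not pass without replicate 5 (adjusted p = 0.0773 and 0.120), with median centring (0.0555 and 0.0826) or with slide as a block (0.283 and 0.252), and mira_rep_c15486 did not pass in a fit of these 5 arrays alone (0.0864). In total 657 contigs changed, 268 higher and 389 lower, and 91 changed more than 2-fold. The count was 292 without replicate 3 and 246 without replicate 5. On the 3 slides, 98.3% to 100% of the contigs had the sign of the call, and 93 passed with slide as a block; 158 passed with median centring and 411 with the centred spike-in covariate. limma called 0 contigs with the unexposed RNA counted as 1 control sample (116 unadjusted), and simulated unchanged animals gave a median of 1806 calls (95% of draws from 95.4 to 3065) against 1 pool but of 0 against separate pools, where 0 of 50 draws reached the real count. The spike-in shift was 0.24 ± 0.55 (SD, n = 5).

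The 4 named falls in silt passed at both doses: mira_rep_c8732 had a log2 change of -3.44 at both 200 and 500 mg/kg, and mira_rep_c17339 of -3.67 ± 0.49 and -2.72 ± 0.49. The 4 named rises passed at 1 dose each: mira_c1844 was at 3.06 ± 0.65 and 0.70 ± 0.65, mira_c23879 at 1.85 ± 0.46 and 0.93 ± 0.46, mira_rep_c11565 at -0.47 ± 0.40 and 1.73 ± 0.40, and mira_rep_c15486 at -0.55 ± 0.39 and 1.58 ± 0.39. Both doses were set against unexposed silt animals, and unchanged animals simulated against 1 silt pool gave a median r of 0.857 between the doses, against -0.10 with separate pools. limma called 0 contigs different between silt 500 and 200 mg/kg, with 293 at an unadjusted p under 0.05. The count stayed at 0 with slide as a block. It was 2 without silt 200 replicate 5, 15 without silt 500 replicate 4 and 1 without silt 500 replicate 5.

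In sand at 10 mg/kg, mira_rep_c22503 rose by 2.75 ± 0.40 (SE, n = 5; 6.72-fold; adjusted p = 2.06e-05) and mira_rep_c17339, which fell in silt, rose by 2.71 ± 0.49 (6.55-fold; adjusted p = 0.000169). mira_rep_c7433 fell by 3.36 ± 0.78 (10.3-fold; adjusted p = 0.00151) and mira_rep_c16217 fell by 3.26 ± 1.19 (9.60-fold; adjusted p = 0.0324). The fall in mira_rep_c16217 did not pass without replicate 1 (-2.74, adjusted p = 0.122), 3 (-3.43, 0.0541) or 4 (-2.60, 0.128), with median centring (-2.955, 0.0642) or with slide as a block (-2.16, 0.320). With the spike-in shift as a covariate, neither fall passed. Tested at a shift of 0, the log2 changes were -2.38 for mira_rep_c7433 (adjusted p = 0.216) and -4.74 for mira_rep_c16217 (0.104), and centred on its mean -2.47 (0.159) and -4.61 (0.0850), so the change in mira_rep_c16217 did not shrink.

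In total 2788 contigs changed in sand at 10 mg/kg, 1451 higher and 1337 lower, with a median fold of 1.31, and 170 changed more than 2-fold. With median centring 69.9% of calls were higher, against 52.0%. On the 4 slides, 96.4% to 99.7% of the contigs had the sign of the call, and 2472 passed with slide as a block. limma called 0 contigs with the unexposed RNA counted as 1 control sample (849 unadjusted), and simulated unchanged animals gave a median of 2208 calls (95% of draws from 565 to 3516) against 1 pool but of 0 against separate pools, where 0 of 50 draws reached the real count. Spike-in RNA was dimmer in the exposed channel, with a shift of -1.19 ± 0.79 (SD, n = 5), and with this shift as a covariate 578 contigs passed, or 769 with the covariate centred on its mean.

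In sand at 60 mg/kg, mira_rep_c24438 fell by 6.18 ± 0.90 (SE, n = 5; 72.7-fold; adjusted p = 3.01e-05) and mira_rep_c9887 fell by 5.72 ± 0.83 (52.7-fold; adjusted p = 2.96e-05). mira_rep_c8305 rose by 1.70 ± 0.21 (3.24-fold; adjusted p = 6.06e-06) and mira_rep_c24062 by 1.64 ± 0.33 (3.11-fold; adjusted p = 0.000553), although in replicate 3 the log2 ratio of mira_rep_c24062 was 0.16 against 1.82 to 2.05 in the others. In total 2633 contigs changed, 1480 higher and 1153 lower, and 204 changed more than 2-fold, 141 of them lower. With median centring 78.5% of calls were higher, against 56.2%. On the 4 slides, 94.2% to 99.96% of the contigs had the sign of the call, and 1470 passed with slide as a block. With the unexposed RNA counted as 1 control sample 1 contig passed, which was none of those named here (adjusted p = 0.373 for both falls, 0.296 and 0.476 for the rises). Simulated unchanged animals gave a median of 2092.5 calls (95% of draws from 498 to 3675) against 1 pool but of 0 against separate pools, where 0 of 50 draws reached the real count. The spike-in shift was -0.52 ± 0.47 (SD, n = 5).

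**Figure D1:**
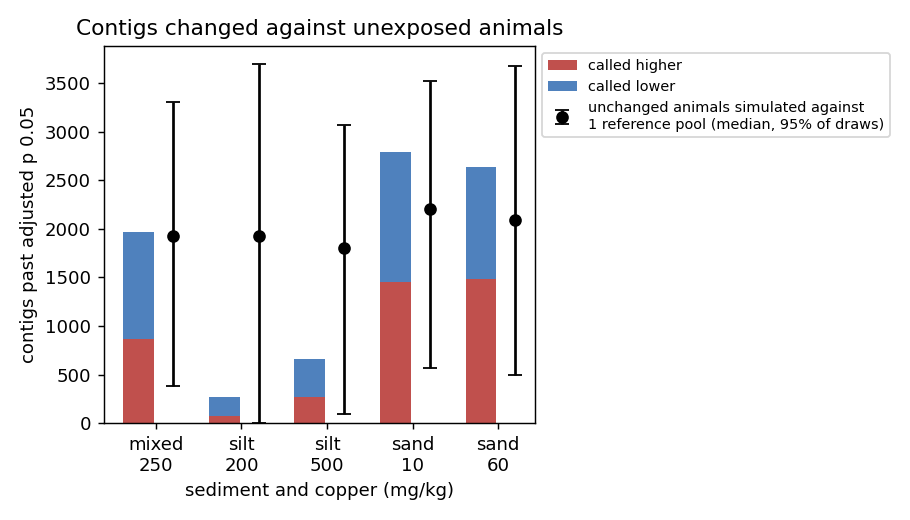
Number of contigs past an adjusted p of 0.05 (vertical axis) in each treatment against unexposed animals, with higher calls in red and lower calls in blue; black points and bars give the median and 95% range of 50 simulated draws of unchanged animals set against 1 unexposed pool per sediment. The observed counts, from 273 to 2788, lie within this range for their treatment, but 0 of 50 draws with separate unexposed pools, not drawn, reached any of them. The simulated pool was given the residual spread of the ratio of 1 array, and the height of the range depends on this choice.

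In the dose comparison within sand, mira_rep_c13549 was lower at 60 than at 10 mg/kg, with a log2 difference of -4.33 ± 0.72 (SE; 20.1-fold; adjusted p = 0.00245), and mira_rep_c17339 likewise, with -4.30 ± 0.70 (19.7-fold; adjusted p = 0.00190). mira_rep_c8514 was higher at 60 mg/kg by 1.72 ± 0.23 (3.29-fold; adjusted p = 0.000540) and mira_rep_c25566 by 1.29 ± 0.18 (2.45-fold; adjusted p = 0.000719). The exposed level of mira_rep_c8514 was 7.28 ± 0.30 (SD, n = 5) on the log2 scale at 10 mg/kg and 9.13 ± 0.41 at 60 mg/kg. In total 73 contigs differed, 17 higher and 56 lower at 60 mg/kg, with a median fold of 2.40, and 44 differed more than 2-fold. Both doses were set against unexposed sand animals, whose level drops out of this comparison only if the same RNA served both doses, which the labels do not state.

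On each of the 3 slides that held both sand doses, all 73 contigs had the sign of the call. With slide as a block 1 contig passed, mira_rep_c8514. The log2 differences under that block were -4.34 for mira_rep_c13549 (adjusted p = 0.0984), -4.36 for mira_rep_c17339 (0.0830) and 1.23 for mira_rep_c25566 (0.0602). In a fit of the 10 sand arrays alone 15 contigs passed, and mira_rep_c13549 (-4.42, adjusted p = 0.0653), mira_rep_c17339 (-4.38, 0.0604) and mira_rep_c8514 (1.67, 0.0604) were not among them, though their differences hardly changed. The count was 38 without sand 10 replicate 3, 40 without sand 10 replicate 5, 43 without sand 60 replicate 3 and 35 without sand 60 replicate 4. With median centring 9.80% of the differing contigs were higher at 60 mg/kg, against 23.3%. Simulated unchanged animals gave 73 or more calls in 0 of 50 draws with 1 unexposed pool per sediment and in 0 of 50 with separate pools.

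Many of the 56 contigs lower at 60 than at 10 mg/kg in sand fell in the other sediments, and they were brighter than most (median log2 intensity 9.26, against 7.90 for all tested). Of these 56 contigs, 41 fell in the mixed sediment (9.29 expected of independent lists), 45 in silt at 200 mg/kg (1.72 expected) and 41 in silt at 500 mg/kg (3.28 expected). In silt at 500 mg/kg 5 of the 56 rose. Over all tested contigs the dose difference correlated with the changes in the mixed sediment at 0.65, but with those in silt at 0.08 (200 mg/kg) and -0.04 (500 mg/kg). At 10 mg/kg in sand, 44 of the 56 rose and 6 fell, values that are part of the difference the 56 were chosen by. Of the 17 contigs higher at 60 mg/kg, 10 rose in the mixed sediment (2.22 expected), 9 in silt at 200 mg/kg (0.177 expected) and 8 in silt at 500 mg/kg (0.687 expected), and 1 fell at each silt dose. A group of 19 contigs, mira_rep_c17339 and mira_rep_c11266 among them, fell in the mixed sediment, in both silts and in sand at 60 mg/kg; 16 of them rose in sand at 10 mg/kg and 0 fell there. In mira_rep_c11266 the log2 changes were -3.05 ± 0.37 in the mixed sediment, -3.35 ± 0.37 and -3.27 ± 0.37 in silt at 200 and 500 mg/kg, 2.09 ± 0.37 in sand at 10 mg/kg and -1.75 ± 0.37 in sand at 60 mg/kg (SE, n = 5 each).

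**Figure D2:**
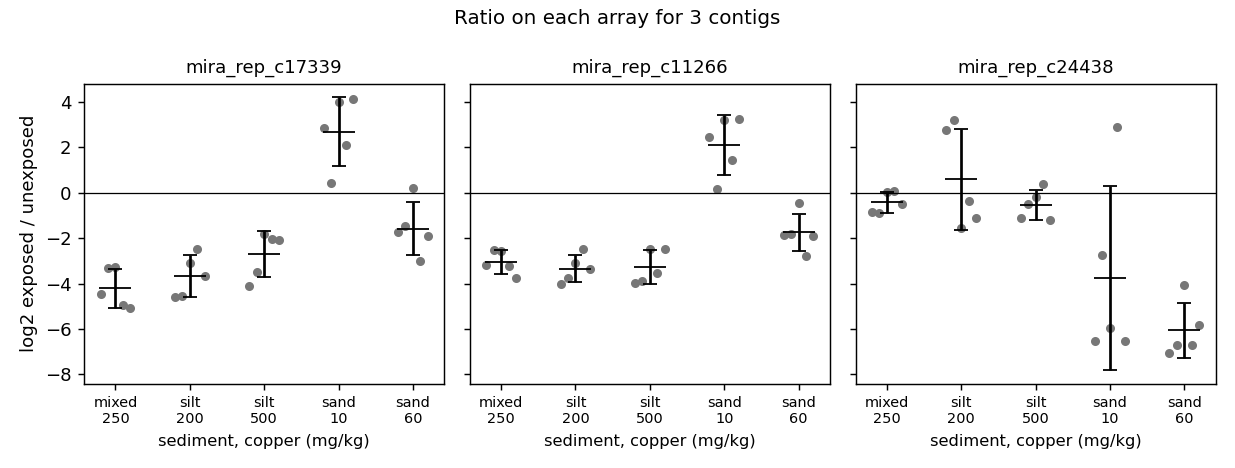
Log2 ratio of exposed over unexposed animals on each array (points, 5 per treatment) with the mean and SD (bars) for mira_rep_c17339, mira_rep_c11266 and mira_rep_c24438, by sediment and copper in mg/kg. mira_rep_c17339 had a fitted change of 2.71 in sand at 10 mg/kg and changes between -4.20 and -1.59 in the other 4 treatments.

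Set side by side, the changes in silt and those in sand differed for many contigs, each relative to unexposed animals of its own sediment. mira_rep_c24438 and mira_rep_c9887, which fell in sand at both doses, were relatively higher in silt, by 4.95 ± 0.90 (SE; adjusted p = 0.000116) and 4.80 ± 0.83 (adjusted p = 7.16e-05). At 10 mg/kg in sand their changes were -3.64 ± 0.90 (adjusted p = 0.00263) and -3.77 ± 0.83 (adjusted p = 0.00102). They were not named there because replicate 4 had the opposite sign (2.90 and 2.12). mira_rep_c13625 was relatively lower in silt, with a difference of -4.93 ± 1.57 (adjusted p = 0.0121), as was mira_rep_c8732 with -4.27 ± 0.39 (adjusted p = 8.50e-08). With slide as a block the differences were 5.39 for mira_rep_c24438 (adjusted p = 0.0685) and -10.24 for mira_rep_c13625 (0.0517), which did not pass though neither shrank. With the spike-in shift as a covariate, in both forms, the differences were 3.44 for mira_rep_c24438 (0.0745), 3.40 for mira_rep_c9887 (0.0564) and -2.34 for mira_rep_c13625 (0.518), and none passed. In total 3492 contigs differed, 1691 higher and 1801 lower in silt, and 30.9% were higher with median centring, against 48.4%. With the spike-in covariate 909 passed, or 906 with it centred. Slide 6 held both sediments, and 97.1% of the contigs had the sign of the call on it; with slide as a block 1303 passed. limma called 0 contigs with the unexposed RNA counted as 1 control sample per sediment (401 unadjusted), and simulated unchanged animals gave a median of 3430.5 calls with 1 pool per sediment and of 0 with separate pools. The copper doses of silt and sand also differ, so sediment and dose are not separated here.

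Against silt, the mixed sediment gave relatively higher values of mira_rep_c7213, by 8.48 ± 2.16 (SE; adjusted p = 0.00816), and of mira_rep_c15791, by 8.35 ± 2.19 (adjusted p = 0.00966). mira_rep_c7213 was well above background in 13 of the 15 exposed samples, so its difference rests partly on dim signal. mira_rep_c15603 was relatively lower, with -5.42 ± 1.23 (adjusted p = 0.00373), as was mira_rep_c8315 with -4.66 ± 1.03 (adjusted p = 0.00306). Without mixed replicates 1 and 5 none of the 4 passed, with differences of 4.41 for mira_rep_c7213 (adjusted p = 0.208), 4.198 for mira_rep_c15791 (0.236), -4.31 for mira_rep_c15603 (0.0645) and -2.81 for mira_rep_c8315 (0.0924), and the count was 804. With slide as a block the differences were larger but did not pass: 13.48 for mira_rep_c7213 (0.0694), 13.44 for mira_rep_c15791 (0.0733) and -8.23 for mira_rep_c15603 (0.0579). In total 1355 contigs differed, 630 higher and 725 lower in the mixed sediment; median centring left 676, of which 66.6% were higher, against 46.5%. On 2 slides 95.6% and 96.6% of the contigs had the sign of the call, and 81 passed with slide as a block, 13.6% of them higher. limma called 0 contigs with the unexposed RNA counted as 1 control sample per sediment (129 unadjusted), and simulated unchanged animals gave a median of 2528.5 calls with 1 pool per sediment and of 0 with separate pools. The copper doses of the mixed sediment and silt also differ, so sediment and dose are not separated here either.

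Against sand, mira_rep_c9887 and mira_rep_c24438 were relatively higher in the mixed sediment, by 4.93 ± 1.02 (SE; adjusted p = 0.000358) and 4.61 ± 1.10 (adjusted p = 0.00144). mira_rep_c17339 was relatively lower, with -4.76 ± 0.60 (adjusted p = 1.08e-06), as was mira_rep_c13549 with -4.72 ± 0.62 (adjusted p = 1.98e-06). With the spike-in shift as a covariate, in both forms, the differences were 3.03 for mira_rep_c9887 (adjusted p = 0.166) and 2.56 for mira_rep_c24438 (0.290), and neither passed. In total 3386 contigs differed, 1546 higher and 1840 lower in the mixed sediment, and 780 differed more than 2-fold. The mixed channels, exposed and unexposed, lay apart from all silt and sand channels on the first axis of channel levels (34.1% of variance). Their scores ran from -46.59 to -26.74, against -7.95 to 20.43. Copper dose, sediment and any other source of this gap are not separated in the contrasts of mixed sediment with silt or sand. With the spike-in covariate 1525 passed in both forms. On 4 slides at least 96.6% of the contigs had the sign of the call, and 3183 passed with slide as a block. With the unexposed RNA counted as 1 control sample per sediment 73 contigs passed, 22 higher and 51 lower. None of the contigs named in this comparison was among them. Their adjusted p was 0.396 for mira_rep_c9887, 0.4997 for mira_rep_c24438, 0.112 for mira_rep_c17339 and 0.1298 for mira_rep_c13549. Simulated unchanged animals gave a median of 2721 calls with 1 pool per sediment and of 0 with separate pools.

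Between the silt doses, log2 changes correlated across the 6636 contigs, which are not independent replicates, with r = 0.84 and a covariance of 0.119. Among contigs, 37 rose at both silt doses (2.79 expected of independent lists), 132 fell at both (12 expected) and 0 moved in opposite directions. Unchanged animals simulated against 1 unexposed silt pool gave a median r of 0.857 (95% of draws from 0.607 to 0.957), a mean covariance of 0.142 and a median of 1175 shared calls; with separate pools the median r was -0.10 (-0.55 to 0.51) and the median of shared calls 0. For the sand doses r was 0.59 and the covariance 0.120, with 1015 contigs higher at both (324 expected), 806 lower at both (232 expected) and 20 opposite. The simulation for sand gave a median r of 0.859 (95% of draws from 0.599 to 0.956), a mean covariance of 0.159 and a median of 1398 shared calls; with separate pools these were a median r of -0.003 (-0.60 to 0.58) and 0 shared calls. The observed covariance minus the simulated mean was -0.022 in silt and -0.039 in sand. The unexposed samples could not be split, so the part of the overlap that comes from the shared controls was not measured apart. Between the mixed sediment and sand at 10 mg/kg r was -0.48, and 1218 contigs moved in opposite directions (416 expected); with sand at 60 mg/kg r was 0.10 but the rank correlation -0.25, and 904 moved in opposite directions (396 expected). Between silt and sand at 10 mg/kg, 151 moved in opposite directions at 200 mg/kg (58.5 expected) and 301 at 500 mg/kg (139 expected). Between silt and sand at 60 mg/kg, 26 (57.5 expected) and 147 (133 expected) did. Between the mixed sediment and silt at 200 mg/kg, 120 fell in both (33.8 expected) and 5 moved in opposite directions (38.1 expected). In all, 2305 contigs were called in no treatment, and 1 contig was higher in all 5.

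**Figure D3:**
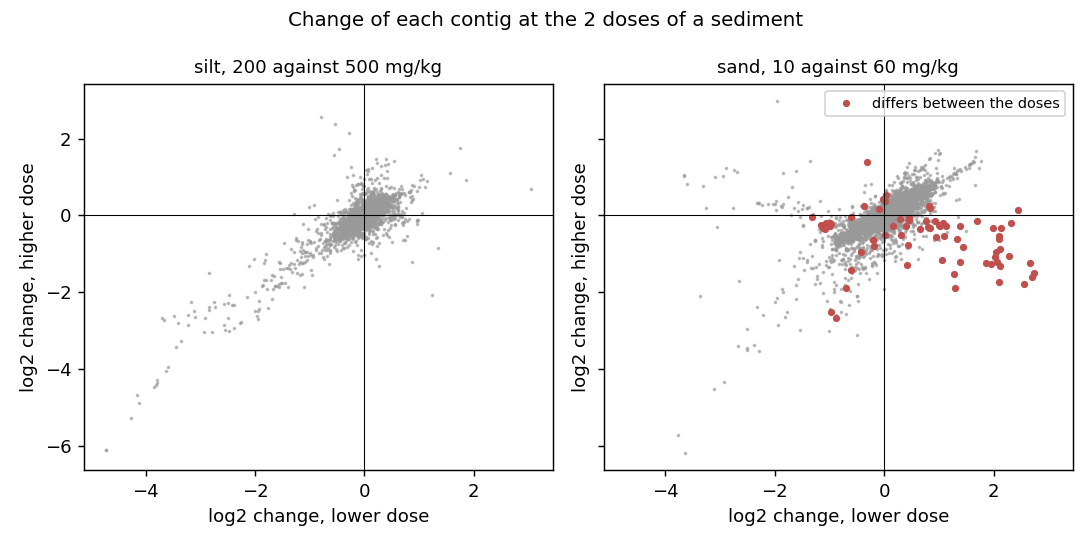
Log2 change of each of 6636 contigs at the lower dose (horizontal axis) and the higher dose (vertical axis) in silt (left) and sand (right), with the 73 contigs that differed between the sand doses in red. Of the 56 contigs lower at 60 than at 10 mg/kg, 44 rose at 10 mg/kg and 30 fell at 60 mg/kg; both doses enter the difference they were chosen by.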

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

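The tests of the reference pool, slide and dye for the shared changes, and of dye for the spike-ins, were chosen after the results were seen, and the last replaced a count of signs (9 of 10 sand arrays below 0); the other tests named here were set before.

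In 50 checks for a sample far from the others, each of 1 measure on the 5 arrays of a treatment, 5 found one. Independent checks would give about 1 in 20 by chance, here 2.5. These checks were not independent, since they reused the same arrays and some were of contigs chosen for large changes. The count of 5 therefore cannot be set against 2.5. Silt 200 replicate 5 correlated with the other arrays of its group at 0.119 (the others 0.426 to 0.533), and silt 500 replicate 2 at 0.146 (0.394 to 0.476). In the mixed sediment replicate 5 stood apart for the contig with the largest rise, at 4.66 (0.257 to 1.46), and for mira_rep_c16585, at 4.61 (0.189 to 1.44). In sand at 60 mg/kg replicate 3 stood apart for mira_rep_c24062, at 0.162 (1.82 to 2.05).

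The 4 contrasts between treatments that called contigs were sand 60 against 10 mg/kg (73), silt against sand (3492), mixed against silt (1355) and mixed against sand (3386). Of 100 splits of the same arrays, the real one included, only the real one reached its own count for the contrasts between sediments. Its counts were 3466 for silt against sand (in a fit with 1 mean per side, highest other 1275), 1362 for mixed against silt (highest other 949) and 3346 for mixed against sand (highest other 1585). A random division of the arrays is excluded at this number of splits. These splits mix arrays of different sediments, and unchanged animals simulated with 1 unexposed pool per sediment gave medians of 3430.5, 2528.5 and 2721 calls. With 1 pool as variable as the ratio of 1 array, the real division would thus stand out without any difference in exposure. With separate pools the medians were 0. For the sand doses 3 of 100 splits, the real one included, gave 73 or more, a share under the 0.05 set for excluding chance. The highest other called 943, several times the real count. This points to a structure among the sand arrays other than dose, so an uneven division of the sand pools is not excluded by the count and is taken up below. For the silt doses the real count is 0, which all 100 splits reach by construction, so the splits say nothing on chance there; the highest called 651, which points to a structure among the silt arrays. For the treatments there are 16 exchanges of exposed and unexposed, too few for a share under 0.05. Only the real assignment, 1 of 16, gave the real count in each. The real and highest other counts were 1969 and 883 in the mixed sediment, 273 and 75 in silt at 200 mg/kg, 657 and 51 in silt at 500 mg/kg, 2788 and 1916 in sand at 10 mg/kg, and 2633 and 751 in sand at 60 mg/kg.

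Changes of treatments that share a sediment ran together: 169 contigs were called the same way at both silt doses (r = 0.84) and 1821 at both sand doses (r = 0.59). Residuals of arrays on the same slide correlated less than those of other slides, by -0.067. The treatment means are taken out of these residuals, and silt and sand lay mostly on different slides. A slide effect common to both doses of a sediment is therefore partly out of their reach, and slide stays open. For dye, the shared sand calls with the dye coefficient were 1.108 times those without it (1821 against 1644). That ratio could not decide. The more frequent dye orientation was opposite at the doses of sand and of silt. An uncorrected dye bias common to the arrays of a sediment would therefore enter its doses with opposite signs. Opposite calls numbered 20 in sand (550 expected of independent lists) and 0 in silt (12.3 expected). This argues against such a bias as the source of the shared calls. A single unexposed pool per sediment stays open and may account for part of the shared changes: the unexposed channel varied between arrays 0.689 times as much as the exposed channel within treatments (95% of resamples from 0.624 to 0.766). Unexposed channels of a sediment also correlated more between arrays, at a mean r of 0.919 in the mixed sediment, 0.822 in silt and 0.773 in sand. Exposed channels within treatments correlated at 0.610, 0.209 and 0.380 in the same order. A steadier unexposed channel would also arise if copper made exposed pools more variable, which was not tested apart. A response common to both doses of a sediment is also open.

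Spike-in RNA stood higher over animal RNA in the unexposed sand channel than in the unexposed silt channel by 0.773 ± 0.191 on the log2 scale (SE, 10 arrays each; two-sided permutation p = 0.00013). If 1 unexposed pool served each sediment, these channels repeat 1 RNA, and the SE and p measure only the spread between labellings and hybridisations. The permutation also exchanged arrays across slides, of which only slide 6 held both silt and sand. With a dye bias common to all arrays already removed, the shift still differed between dye orientations, in opposite directions in sand and silt. Its mean was -0.38 on the 5 sand arrays with exposed RNA in Cy3 and -1.33 on the 5 in Cy5, and -0.10 and 0.62 on those of silt. A dye bias cancels in the mean over both orientations, and that mean still differed between sand and silt by -1.113 ± 0.176, which argues against dye as the source of the difference between the sediments. A lower yield of labelled RNA from unexposed sand animals may be the source, but it cannot be told apart because 0.773 does not exceed the bound of 0.5 by 2 SE. A higher yield from exposed sand animals cannot be told apart either, at -0.258 ± 0.187 (permutation p = 0.18). No biological explanation was tested.

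The sand dose difference correlated across contigs, at r = -0.60, with the main axis of the residual ratios of the 15 silt and mixed arrays. This axis held 36.2% of their variance, and its sign is arbitrary. Uneven pools stay open: 9 of 100 splits of the 10 sand arrays, the real one included, gave a correlation at least as far from 0, the highest 0.713. The sand groups may therefore differ for reasons other than dose. Without the 332 contigs with the largest loadings, 5% of those tested, the correlation was 0.052. Leaving out the extremes of the axis lowers a correlation with that axis in itself. Whether a small set of very variable contigs carries the correlation is therefore not settled by this test. An effect of the copper dose itself remains open beside these.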

How the results depend on the processing

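The settings with 1 control sample, scan day, the spike-in shift and without arrays that stood apart were chosen after seeing the data. Counts are given in the order of the report, and where not stated the cause was not tested.

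Counting the unexposed RNA as 1 control sample, which adds the control's spread, lowered most counts: to 5 in the mixed sediment, 0 in both silts and in sand at 10 mg/kg, 1 in sand at 60 mg/kg, 0 for silt against sand, 0 for mixed against silt and 73 for mixed against sand. limma called 89, 116, 849, 401 and 129 contigs at an unadjusted p under 0.05 where the count was 0. The dose contrasts cannot change under this setting by construction, so the 73 for the sand doses is no evidence of stability.

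With slide as a fixed block, which leaves fewer degrees of freedom, counts were 152 and 93 in the silts, 1470 in sand at 60 mg/kg, 1 for the sand doses, 1303 for silt against sand and 81 for mixed against silt. As a random block slide moved no count past 1.5 times (correlation -0.047). Median centring gave 92 and 158 in the silts and 676 for mixed against silt. No background correction gave 535 in silt at 200 mg/kg and 2 for the silt doses, which were 3 with processed signals and 2 with the authors' table. Fitting only the groups compared, with fewer samples, gave 0 in silt at 200 mg/kg (1230 unadjusted) and 15 for the sand doses.

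The spike-in shift as a covariate gave 578 in sand at 10 mg/kg, 909 for silt against sand and 1525 for mixed against sand; centred on its mean it gave 1217 in the mixed sediment, 411 in silt at 500 mg/kg, 769 in sand at 10 mg/kg, 906 and 1525. Without mixed replicates 1 and 5, which had low axis scores, the mixed sediment had 1273 and mixed against silt 804. Scan day as a block and leaving out the 2 silt arrays that stood apart moved no count past 1.5 times.

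Leaving out 1 array at a time gave 110 to 277 in silt at 200 mg/kg, 246 to 671 in silt at 500 mg/kg, 0 to 15 for the silt doses and 35 to 80 for the sand doses; the other counts stayed within 1.5 times. Replicate numbers did not pair the samples: same-numbered arrays correlated at a mean of 0.021, 21 of 50 pairs exceeded 0.1, and 6 of 25 arrays correlated best with their own number. With the replicate number as a block, the counts were 1987, 269, 582, 2802, 2651, 0, 59, 3485, 1323 and 3408, none moved past 1.5 times.

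No named contig changed sign. Apart from the 1 control sample, calls of named contigs held in 476 fits under other settings and were lost in 52, and held in 325 and were lost in 15 with 1 array left out. With 1 control sample 32 were lost, and the other 4 belong to the sand dose contrast, which that setting does not change. The settings with 1 probe per target and the gene list tests, with their estimated correlation, were not run. Dim signal limits the rest: 1876 of 8512 probes were too dim to test.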

Other observations

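The comparisons of unexposed levels and the contigs singled out here were chosen after their values were seen.

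Unexposed levels of some named contigs differed between sediments. The level of mira_rep_c17339 was 16.36 ± 0.13 (SD, n = 5, log2) in unexposed mixed sediment, 16.10 ± 0.22 (n = 10) in unexposed silt and 12.04 ± 0.21 (n = 10) in unexposed sand. Exposed animals had 12.15 ± 0.83 in the mixed sediment, 12.45 ± 0.78 and 13.37 ± 1.19 in silt at 200 and 500 mg/kg, 14.64 ± 1.38 in sand at 10 mg/kg and 10.55 ± 1.11 in sand at 60 mg/kg (n = 5 each). All 19 contigs that fell in the mixed sediment, both silts and sand at 60 mg/kg were lower in unexposed sand than in unexposed silt, with a median difference of -3.34; unexposed silt is the denominator of the ratios they were chosen by, so this comparison is coupled to the choice. Of the 56 contigs lower at 60 than at 10 mg/kg in sand, 50 were lower in unexposed sand (median -1.84), against 45.9% of all tested contigs (median 0.02). For mira_rep_c24438 the order was opposite: 14.21 ± 0.42 in unexposed sand, 8.95 ± 0.25 in unexposed silt and 8.23 ± 0.14 in unexposed mixed sediment, with 8.24 ± 1.09 in sand at 60 mg/kg.

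Some contigs were bright in some exposed pools and near background in others of the same treatment. mira_rep_c7213 ranged from 6.87 to 18.61 over the exposed pools, with a pooled SD within treatments of 4.01, against 0.48 in the unexposed channel within sediments; the median exposed SD of all tested contigs was 0.189. Its unexposed level was 8.09 ± 0.35 in the mixed sediment, 16.94 ± 0.45 in silt and 16.83 ± 0.55 in sand. On the main axis of the residual ratios of the 15 silt and mixed arrays, mixed replicates 1 and 5, silt 200 replicate 5 and silt 500 replicate 2 scored -19.95, -33.57, -27.88 and -39.84. The other 11 lay between -0.2 and 19.89.

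Relative to the mean of all arrays in the same dye, spike-in RNA over animal RNA stood at 3.04 ± 0.52 (SD, n = 5, log2) in exposed mixed sediment. In unexposed mixed sediment it stood at 2.06 ± 0.10, and between -1.0 and 0.17 in the group means of both channels of silt and sand. These values are departures from that mean and not the height of spike-in signal over animal signal. They were taken before loess, and the shift of 0.66 for the mixed sediment after it.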
